A study of Mus musculus with 8 samples.

How the data were processed

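RNA from the left ventricle of 8 mice was sequenced, 4 fed normal chow and 4 fed a high-fat diet with 0.5% L-NAME, an inhibitor of nitric oxide synthases, for 9 weeks from 12 weeks of age. Per the labels' protocols, tissue was frozen on dry ice, RNA was taken with a fibrous tissue reagent, and libraries were made from total RNA with the Illumina TruSeq RNA kit. The labels write the strain as C57BL/5NJ. They give no sex, genotype, batch or date for any library, so none of these could be set against the groups from the labels. Xist had 0 to 11 counts in each library and Tsix, on its opposite strand, 3 to 180. As the strand setting is not given and no Y-linked gene has a named row, the sex of the mice was left open. Each library was matched to its column through the mouse number in its title, and replicates were numbered in accession order, which pairs no samples. The labels give each library its own mouse number.

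The authors deposited a table of raw counts per gene, and per the submitters' processing notes bcl2fastq 1.8.4, Trim Galore 0.4.0, STAR 2.6 and DESeq2 1.22.1 were used. Those notes name a human genome build, whereas the deposited row names are those of the C57BL/6NJ mouse strain annotation. No coordinates are given for this reason. The counting step, its strand setting and its filters are not given in the sources used here, so reads of overlapping genes on opposite strands cannot be told apart. The authors also deposited a table with log2 fold changes, a test score per gene, p-values and adjusted p-values. In that deposited table each p-value equals the upper tail of a chi-square distribution with 1 degree of freedom at the score, as a likelihood ratio test gives. The normalised values in its 8 per-sample columns were not used.

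Gene names were taken from the authors' deposited table, and symbols not found there were matched through RefSeq synonyms. For the ribosomal list this matched 2 other genes, F2 for Rpl3 and Rps27rt for Rps27. F2 was not among the 48 members tested in the edgeR fit of all 8 libraries. Without both matches the list had 47 genes and a camera adjusted p of 0.0650, and 14 lists passed as before. The count table held 41096 genes, of which 22403 had a count and 14875 were tested, 13782 of them with a name. Rows without a name held 9.19% to 10.5% of the counts of a library and were kept. Mitochondrially encoded mRNAs and Y-linked genes have no named row, so the mitochondrial share of the counts was not analysed here, and the fixed list of mitochondrially encoded mRNAs could not be tested. Total counts ranged from 31522074 to 52053633 per library. Intervals on counts are exact Poisson intervals at 95% and cover counting error only.

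Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM factors, the filterByExpr filter with its minimum count of 10, no covariate, Benjamini-Hochberg adjustment, threshold 0.05). CPM values use TMM-scaled totals. Standard errors are the log2 fold change divided by the square root of the F statistic. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over 35 lists of at least 3 measured members. Pathway lists and lists of markers of other cell types were fixed before the data were examined. Some genes stand in more than 1 list, such as Cidea and Cidec among both PPAR targets and adipocyte markers. Library totals and shares were compared with a two-sided exact permutation test over 70 arrangements, whose smallest p is 0.0286.

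Named genes follow a rule also fixed before the data were examined. It takes up to 10 genes per direction past the threshold with a mean of at least 5 CPM and groups that do not overlap, then up to 4 members with the smallest p from each list past the threshold, and a set of genes of the heart, of fuel use and of the nitric oxide system. Genes outside the rule are said to be so, and 1 gene that the rule names is not reported here. No 2 libraries of a group agreed within sampling noise, with a chi-square per degree of freedom between 27.1 and 69.1.

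The steps were tested on simulated data for this comparison, with 14875 genes, 200 of them changed in each of 3 simulations. edgeR recovered 67.3% of genes changed 2-fold and 84.3% of genes changed 4-fold, and 4.61% of its calls were false. With DESeq2 1.42.0 the shares were 74.3% and 88.7%, with 18.1% false calls, and with limma-voom they were 66.3% and 82.0%, with 5.12% false calls. Each gene was drawn independently with the dispersion that edgeR fitted, without variation shared between genes. The shares of all tools hold for that setting only.

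The alternatives were DESeq2 and limma-voom, other scalings and filters, stricter thresholds, a surrogate variable from sva 3.50.0, other gene set tests, and leaving out each library. Alternatives chosen after seeing the data were a robust edgeR fit, DESeq2's likelihood ratio test, thinning all libraries to the smallest total, scores of atrial and adipocyte markers as covariates, fits without the libraries highest in those markers, the PPAR list without members shared with adipocytes, the hypertrophy list without atrial members, the ribosomal list without those 2 matches, and the Ighg2c ratio without 1 treated library.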

Results

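The study sequenced left ventricular RNA from mice given a high-fat diet with L-NAME, a treatment used to model heart failure with preserved ejection fraction, and from mice on normal chow. Each group held 4 libraries. The series design also describes cohorts with and without Nnt, the mitochondrial transhydrogenase that makes NADPH, but the labels of these 8 libraries carry no such genotype. Total counts averaged 48620000 ± 4760000 in chow and 36680000 ± 3938000 with HFD+L-NAME (SD, n = 4 each). Depth thus differed between the groups (two-sided exact permutation p = 0.0286 with n = 4 each, the smallest the design allows). Genes detected per library averaged 17410 ± 572 and 17860 ± 660 (exact permutation p = 0.314). The 10 most abundant genes took 17.6 ± 0.289% and 17.0 ± 0.680% of the counts (n = 4 each, exact permutation p = 0.171).

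The comparison of HFD+L-NAME with chow asked which transcripts of the ventricle differ after 9 weeks of the diet. Tmem150c, a membrane protein gene linked to mechanically activated currents, fell from 18.5 ± 2.36 to 8.74 ± 0.793 CPM (SD, n = 4 each), a log2 fold change of -1.08 ± 0.13 (SE; edgeR adjusted p = 0.0350). It was lower in all 4 treated libraries than in any chow library. Ighg2c, an immunoglobulin heavy chain constant gene named here after its values were seen, rose from 1 count in the 4 chow libraries together to 1062 counts in the 4 treated ones (edgeR adjusted p = 0.0393). The ratio of its pooled rates was 1402, with a counting interval from 251 to 55430. HFD+L-NAME 3 held 744 of these counts, and without it the ratio was 541 (96.5 to 21440). Its adjusted p was 0.0629 with all libraries thinned to the smallest total, 0.0787 with the surrogate variable, 0.145 with the robust edgeR fit and 0.298 with limma-voom, so the call ended in each, and DESeq2 gave Ighg2c no adjusted p. Tmem150c missed the threshold with limma-voom (0.0875). Both genes missed it in edgeR fits chosen after seeing the data, with Ighg2c first and Tmem150c second in each pair. These fits had a score of atrial markers as a covariate (0.0638 and 0.0638), one of adipocyte markers (0.281 and 0.281), or left out HFD+L-NAME 2 and 3 (0.0649 and 0.232). The adipocyte score follows the groups (correlation 0.825), so its fit cannot separate adipose tissue from the treatment. Without the 5 libraries with atrial transcripts a lone treated library is left, and Tmem150c had a log2 fold change of -1.32. Of the 8 fits without 1 library, Ighg2c and Tmem150c each passed in 2. Of 14875 genes tested, these were the 2 that passed, 1 higher and 1 lower. An unadjusted p under 0.05 was found for 1422 genes, and 889 genes, or 5.98%, had groups that did not overlap, against 2.86% by chance. DESeq2 called 161 genes and limma-voom 0. The edgeR count ranged from 0 to 3 when single libraries were left out, going to 0 without chow 1, chow 2, chow 4, HFD+L-NAME 2 or HFD+L-NAME 4 and to 1 without HFD+L-NAME 1.

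**Figure D1:**
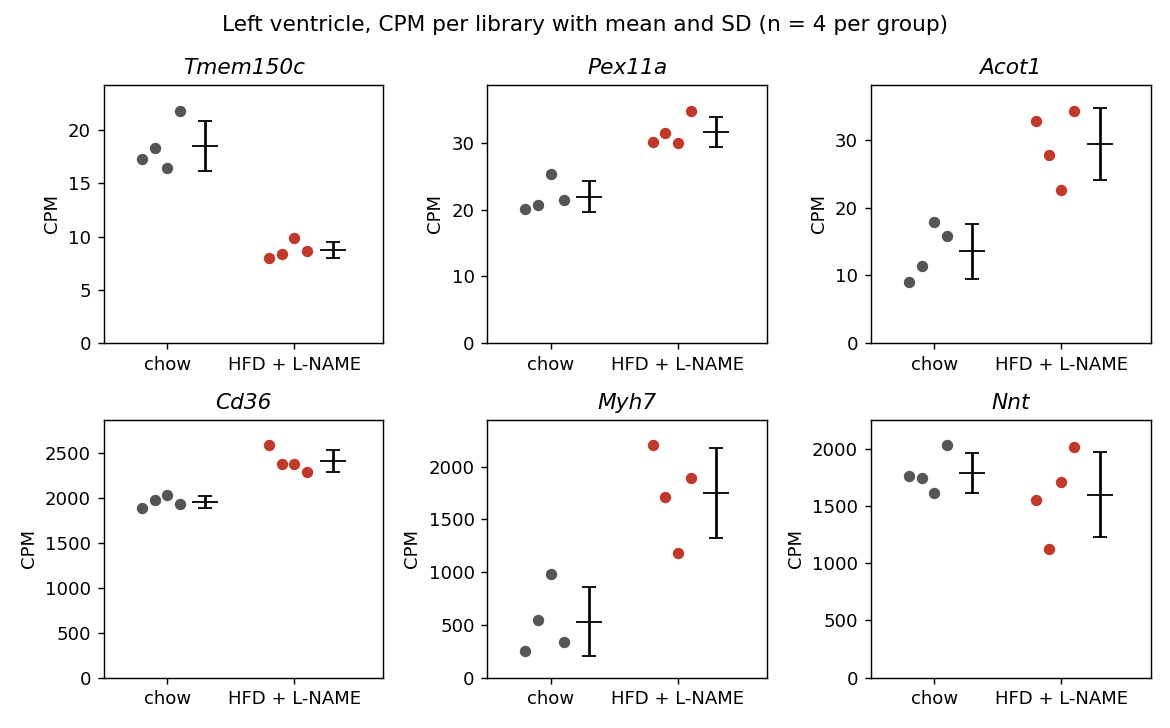
Expression in CPM of Tmem150c, Pex11a, Acot1, Cd36, Myh7 and Nnt in each left ventricle library (points), with the group mean and SD beside them (n = 4 per group). Tmem150c averaged 18.5 CPM in chow and 8.74 CPM with HFD+L-NAME, and of these 6 genes it alone passed the edgeR threshold.

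Targets of PPAR, the nuclear receptors that respond to fatty acids, rose as a list with HFD+L-NAME (24 members tested, median log2 fold change 0.26, camera adjusted p = 3.23e-09; adjusted p = 0.423 with an estimated correlation). Over all genes tested edgeR called 0 members (13 had an unadjusted p under 0.05), limma-voom 0 and DESeq2 4, all higher: Acot1, Cidec, Pex11a and Cd36. With edgeR, 7 rose when adjusted over the list alone. The acyl-CoA thioesterase gene Acot1 averaged 13.5 ± 4.03 CPM in chow and 29.4 ± 5.29 CPM with treatment (SD, n = 4 each; log2 fold change 1.12 ± 0.20, edgeR adjusted p = 0.178), with the limit that it has a close paralog in Acot2. Pex11a, a peroxisome gene, had a log2 fold change of 0.53 ± 0.10 and the fatty acid transporter Cd36 one of 0.30 ± 0.07. In Acot1, Pex11a and Cd36 all 4 treated libraries lay above all 4 chow libraries. Pdk4 (0.62 ± 0.28), Angptl4 (0.69 ± 0.38) and Ucp3 (0.18 ± 0.21) did not pass with edgeR. Without HFD+L-NAME 1 their log2 fold changes were 0.33, 0.085 and -0.039.

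Genes of fatty acid oxidation rose as a list (24 tested, median log2 fold change 0.17, camera adjusted p = 0.000157; adjusted p = 0.628 with an estimated correlation). Over all genes edgeR called 0 members (11 had an unadjusted p under 0.05), limma-voom 0 and DESeq2 6, 5 higher and 1 lower. With edgeR, 6 rose and 1 fell when adjusted over the list alone. Hadha, the alpha subunit of the mitochondrial trifunctional protein, averaged 2321 ± 231 CPM in chow and 2918 ± 154 CPM with treatment (SD, n = 4 each). The log2 fold changes of Ech1, Decr1 and Hadha were 0.43 ± 0.10, 0.40 ± 0.09 and 0.33 ± 0.08, and that of the acyl-CoA synthetase gene Acsl6 was -0.65 ± 0.14. Lists of other fuel pathways fell: ketone and branched-chain amino acid breakdown (21 tested, median -0.14, camera adjusted p = 0.00114), nuclear-encoded oxidative phosphorylation (67 tested, median -0.08, adjusted p = 0.00229) and glucose uptake and glycolysis (21 tested, median -0.07, adjusted p = 0.00335). With an estimated correlation their adjusted p were 0.628, 0.782 and 0.628. With edgeR 0 members passed over all genes or when adjusted over the list alone (4, 1 and 4 had an unadjusted p under 0.05). Over all genes limma-voom called 0 members of these lists and DESeq2 called 1, the glycolysis gene Eno3, lower. The muscle enolase gene Eno3 averaged 2063 ± 251 and 1540 ± 206 CPM, and Bcat2, which starts branched-chain amino acid breakdown, averaged 221 ± 33.6 and 175 ± 4.37 CPM (SD, n = 4 each). Without HFD+L-NAME 3 the camera direction of oxidative phosphorylation turned (adjusted p = 0.841) and glycolysis did not pass (adjusted p = 0.102), and without chow 4 oxidative phosphorylation did not pass (adjusted p = 0.0656). Oxidative phosphorylation passed in the other direction, higher, with a score of adipocyte markers as a covariate (camera adjusted p = 4.38e-09) and without HFD+L-NAME 2 and 3 (0.0220), settings chosen after seeing the data. In these settings ketone breakdown and glycolysis did not pass: their directions turned with the adipocyte score (0.450 and 0.502), and without HFD+L-NAME 2 and 3 they had 0.514 and 0.514. The adipocyte score follows the groups (correlation 0.825), so the reversals with it cannot be separated from the treatment. The 3 fuel lists, in the order above, had camera adjusted p of 0.0587, 0.189 and 0.0794 with the atrial score.

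Markers of adipocytes rose as a list with HFD+L-NAME (12 tested, median log2 fold change 2.35, camera adjusted p = 1.65e-06; adjusted p = 0.423 with an estimated correlation). With edgeR, 9 rose and 1 fell when adjusted over the list alone. Over all genes edgeR called 0 (10 had an unadjusted p under 0.05), limma-voom 0 and DESeq2 4, 3 higher and 1 lower. Plin1, the coat protein of fat droplets, stood at 12.0 and 8.73 CPM in HFD+L-NAME 2 and 3, at 1.60 and 2.57 CPM in HFD+L-NAME 1 and 4, and at 0.444 to 2.13 CPM in chow. Ucp1, a marker of the list that the low-count filter left out of the test, is named here after its values were seen. It had 487 and 166 counts in HFD+L-NAME 2 and 3, 0 in HFD+L-NAME 1 and 4, and 0 to 14 in chow. Thrsp went the other way, with 31.5 ± 2.84 CPM in chow and 19.1 ± 3.17 CPM with treatment (SD, n = 4 each; log2 fold change -0.72 ± 0.13, edgeR adjusted p = 0.178). Atrial and conduction tissue markers also rose as a list (12 tested, median 0.59, camera adjusted p = 0.00545; adjusted p = 0.628 with an estimated correlation). Its direction turned with the adipocyte score (camera adjusted p = 0.0747), which follows the groups, and it did not pass without HFD+L-NAME 2 and 3 (0.698). Over all genes edgeR called 0 of its members (1 had an unadjusted p under 0.05), limma-voom 0 and DESeq2 1, Nr2f2, higher. The atrial myosin light chain Myl7 was at 290 and 283 CPM in chow 1 and 3 and at 216 to 686 CPM in HFD+L-NAME 2, 3 and 4, against 0.714 and 1.02 CPM in chow 2 and 4 and 10.2 CPM in HFD+L-NAME 1. PPAR targets and adipocyte markers share Cidea and Cidec. The PPAR and fatty acid oxidation lists were tested on libraries that differed in both marker groups in this way.

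**Figure D2:**
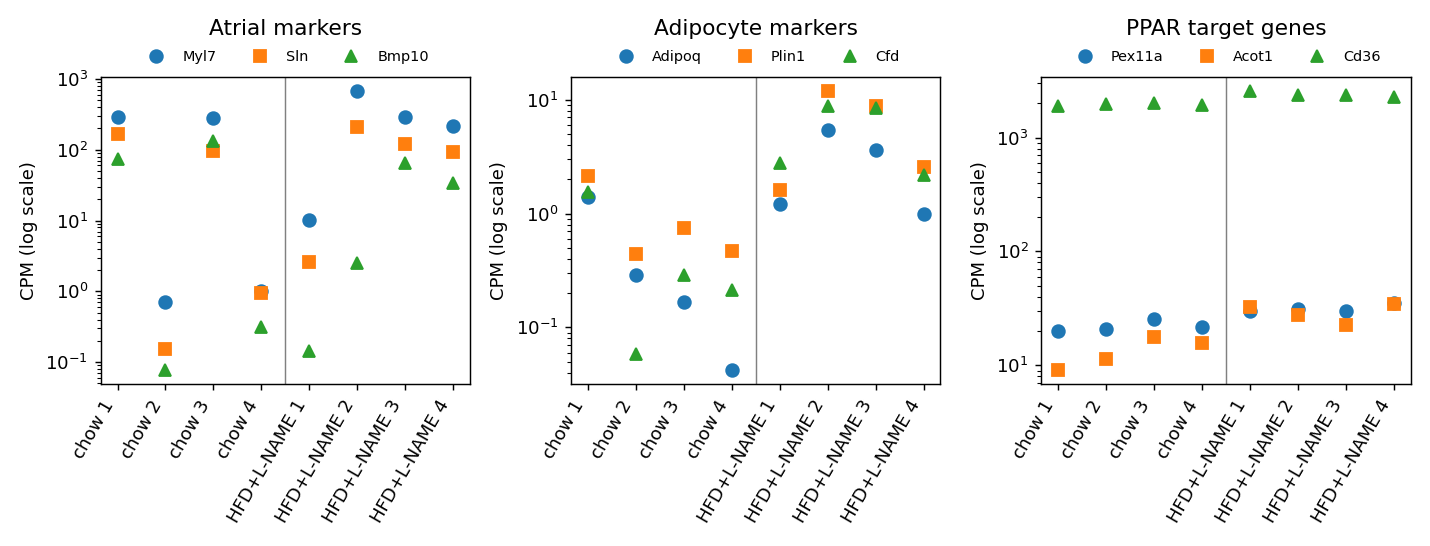
CPM on a log axis of 3 atrial markers, 3 adipocyte markers and 3 PPAR target genes in each of the 8 libraries, with a line between chow and HFD+L-NAME. Myl7 ranged from 0.714 to 686 CPM without following the groups, and Plin1 was highest in HFD+L-NAME 2 at 12.0 CPM.

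The hypertrophy and fetal gene list rose (20 tested, median log2 fold change 0.31, camera adjusted p = 0.0157; adjusted p = 0.628 with an estimated correlation). With edgeR, 2 members rose when adjusted over the list alone. Over all genes edgeR called 0 (6 had an unadjusted p under 0.05), limma-voom 0 and DESeq2 2, Mybpc2 and Myh7, both higher. Myh7, the slow beta myosin heavy chain, averaged 531 ± 326 CPM in chow and 1747 ± 428 CPM with treatment (SD, n = 4 each), a log2 fold change of 1.72 ± 0.36 (edgeR adjusted p = 0.209), with all treated libraries above all chow libraries and with reads that counting could share with Myh6. Myh6, the main adult myosin, had a log2 fold change of -0.07 ± 0.10, Acta1 0.40 ± 0.61 and the natriuretic peptide genes Nppa and Nppb 0.36 ± 0.79 and -0.57 ± 0.36. Nppa, Myl4 and Myl7 are members of the list and also atrial transcripts. Without these 3 the list had a median of 0.21 over 17 genes (camera adjusted p = 0.0341; 0.628 with an estimated correlation), a choice made after seeing the data. The direction of the full list turned with the adipocyte score (camera adjusted p = 0.943), which follows the groups. It turned too without the 5 libraries with atrial transcripts, where a lone treated library is left. The full list did not pass with the atrial score (0.198) or without HFD+L-NAME 2 and 3 (0.662). Nppa was at 486 to 2413 CPM in the 5 libraries with Myl7 above 200 CPM and at 136 to 307 CPM in the 3 others.

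Extracellular matrix and fibrosis genes rose as a list (42 tested, median log2 fold change 0.18, camera adjusted p = 0.000709; adjusted p = 0.628 with an estimated correlation). With edgeR 0 members passed either adjustment (7 had an unadjusted p under 0.05), and over all genes limma-voom and DESeq2 called 0. Col1a1 (0.23 ± 0.26), Col3a1 (0.08 ± 0.29) and Postn (0.72 ± 0.29) did not pass with edgeR. The list's adjusted p was 0.112, 0.140 and 0.140 without HFD+L-NAME 2, HFD+L-NAME 3 and chow 4. Its direction turned with the adipocyte score as a covariate (camera adjusted p = 1.69e-08), which follows the groups, and without HFD+L-NAME 2 and 3 (0.0504). It turned too without the 5 libraries with Myl7 above 200 CPM, where a lone treated library is left. The list did not pass with the atrial score (0.251). All these settings were chosen after seeing the data. Further lists past the threshold were smooth muscle and pericyte markers (higher, 0.00545), immediate early genes (higher, 0.0143), endothelial markers (higher, 0.0194), lymphatic endothelial and Schwann cell markers (higher, 0.0436) and cell cycle genes (lower, 0.0442), each by camera adjusted p. Their adjusted p with an estimated correlation were 0.628, 0.628, 0.602, 0.628 and 0.628. Without those 5 libraries, where a lone treated library is left, the directions of immediate early and cell cycle genes turned. With the adipocyte score the adjusted p were 0.0511 for smooth muscle, 0.338 for endothelial, 0.986 for lymphatic and 0.0511 for cell cycle genes. Without HFD+L-NAME 2 and 3 they were 0.126 for immediate early, 0.157 for endothelial, 0.308 for lymphatic and 0.178 for cell cycle genes. Over all genes edgeR, limma-voom and DESeq2 called 0 members of these 5 lists, where edgeR gave 4 smooth muscle, 4 immediate early, 3 endothelial, 5 lymphatic and 0 cell cycle genes an unadjusted p under 0.05. In the smooth muscle list 2 members were higher and 1 lower with edgeR when adjusted over the list alone. Myh11 averaged 36.5 ± 12.7 and 86.0 ± 38.1 CPM and Tagln 18.8 ± 7.17 and 49.5 ± 24.0 CPM (SD, n = 4 each). Leaving out 1 library, the lists passed in all 8 fits for smooth muscle, in 6 for endothelial markers, in 4 each for immediate early genes and atrial markers, and in 3 each for hypertrophy, lymphatic and cell cycle genes. The highest adjusted p in these fits were 0.0656 (endothelial, without chow 4), 0.519 (immediate early, without chow 1), 0.120 (atrial, without chow 2), 0.117 (hypertrophy, without HFD+L-NAME 2), 0.200 (lymphatic, without chow 4) and 0.217 (cell cycle, without HFD+L-NAME 3). In all, 14 of 35 lists passed, and 0 did with an estimated correlation.

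The lists that did not pass had camera adjusted p of 0.0652 for cytosolic ribosomal proteins, 0.0652 for lipid and cholesterol synthesis, 0.0920 for hypoxia, 0.115 for calcium handling, 0.128 for lymphocyte markers, 0.128 for macrophage markers, and 0.128 for inflammatory mediators. They were 0.137 for the tricarboxylic acid cycle, 0.137 for the nitric oxide system, 0.137 for NADPH supply and peroxide removal, 0.137 for corticoid targets, 0.146 for the sarcomere, 0.160 for the circadian clock, and 0.180 for neutrophil markers. The highest were 0.464 for fibroblast markers, 0.483 for interferon response, 0.496 for heat shock, 0.753 for the unfolded protein response, 0.794 for NRF2 targets, 0.995 for mesothelial and valve markers and 0.998 for erythrocyte markers. The median and the test differed in sign for macrophage markers, the unfolded protein response and mesothelial markers, and the mean and the test did for calcium handling, heat shock and mesothelial markers. Nnt averaged 1785 ± 175 CPM in chow and 1599 ± 373 CPM with treatment (SD, n = 4 each), a log2 fold change of -0.16 ± 0.15 (edgeR adjusted p = 0.785). Log2 fold changes were -0.0045 ± 0.12 for Xbp1, -0.16 ± 0.11 for Hspa5, -0.19 ± 0.14 for Nos2, 0.19 ± 0.10 for Nos3, -0.31 ± 0.14 for Slc2a4, -0.16 ± 0.19 for Slc2a1, -0.07 ± 0.08 for Atp2a2, 0.11 ± 0.08 for Ttn and -0.01 ± 0.10 for Rbm20, and none of them passed with edgeR.

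The authors' deposited table gives the same comparison by DESeq2's likelihood ratio test. There, 156 genes of the authors' deposited table had an adjusted p under 0.05, 82 higher and 74 lower. Of these, 152 were tested with edgeR, all 152 with the same sign, and 1 passed there. The authors' deposited table lists Tmem150c at a log2 fold change of -1.08 (adjusted p = 9.15e-09), Acot1 at 1.12 (0.000111), Pex11a at 0.53 (0.00408), Cd36 at 0.30 (0.00655), Hadha at 0.33 (0.0288) and Myh7 at 1.72 (0.0443).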

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

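All tests in this part were chosen after the result was seen, except the split counts of genes called by edgeR and by DESeq2's Wald test and of lists. Predictions for the further atrial genes and for the splits of the PPAR list were written before those tests were run. Both name a pattern of these data, the libraries high in Myl7 and the rise of the PPAR list.

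PPAR target genes were higher with HFD+L-NAME, and adipocyte markers were highest in HFD+L-NAME 2 and 3, with a mean log2 CPM in HFD+L-NAME 1 and 4 (1.13 and 0.64) also above the highest chow value, 0.54. Adipose tissue in libraries 2 and 3 alone would leave the list at its chow level without them, yet the list without the members shared with adipocytes kept a median log2 fold change of 0.32 over 23 genes (camera adjusted p = 1.20e-08; adjusted p = 0.852 with an estimated correlation). Adipose tissue in all 4 treated libraries stays open. With the adipocyte score as a covariate the same list kept a median of 0.49 (camera adjusted p = 7.76e-11, and 0.135 with an estimated correlation). That fit cannot separate adipose tissue from the treatment, since the score follows the groups (correlation 0.825). Lower depth of the treated libraries is argued against by thinning all of them to the smallest total (camera adjusted p = 2.82e-09, and 0.513 with an estimated correlation). Of the 35 splits of the libraries into 4 and 4, 1, the real one, gave a camera p as small (9.21e-11, against 3.56e-08 in the next). That share is the smallest that 35 splits can give. The list also had the smallest p of the 35 lists tested, so chance is not excluded for it. A response of the ventricle to HFD+L-NAME is a candidate explanation, found and tested on the same data.

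Atrial transcripts were present in 5 of the 8 libraries, from both groups. A response to HFD+L-NAME as the whole cause is argued against by 2 chow libraries with a higher atrial score than the lowest treated library. Of 5 further atrial genes, 4 (Kcnj5, Pam, Gja5 and Hamp, the last at no more than 1.58 CPM) had those 5 libraries above the other 3. Atrial tissue in the dissected samples would give this. A random order of libraries gives 1.79% for a gene, but the share over all tested genes was not computed and may be higher. The first principal component of all tested genes, with 23.6% of the variance, also set those 5 libraries apart from the other 3. The source may not be 1 uniform piece, since Bmp10 was at 2.54 CPM in HFD+L-NAME 2 and 133 CPM in chow 3, beside Myl7 at 686 and 283 CPM.

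Ighg2c had 95, 105, 744 and 118 counts in HFD+L-NAME 1 to 4 and 0, 0, 1 and 0 in chow. Plasma or B cells bring light chains too, which fits HFD+L-NAME 3, where the ratio of Ighg2c to light chain counts was 0.518. In HFD+L-NAME 1 and 4 the ratios were 9.50 and 2.15, which cannot decide against such cells. Ighm, a heavy chain gene of B cells, also exceeded the light chain counts in every library but HFD+L-NAME 3. It had 321 counts against 49 in chow 1 and 264 against 10 in HFD+L-NAME 1. Plasma or B cells thus stay open as a source in HFD+L-NAME 1 and 4. In HFD+L-NAME 2 the ratio was 0.882 with overlapping counting intervals, which decides nothing, and chow held 19 to 79 light chain counts with at most 1 of Ighg2c. Adipose tissue in HFD+L-NAME 2 and 3 alone is argued against by the 2 other treated libraries, both above the counting bound of every chow library. Adipose tissue in all 4 treated libraries stays open. The adipocyte scores of HFD+L-NAME 1 and 4 (1.13 and 0.64) were also above the highest chow score (0.54). With that score as a covariate Ighg2c had an edgeR adjusted p of 0.281. Light chain rows without a name, and a response to HFD+L-NAME, stay open as possible explanations and were not tested.

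Of 35 splits, 2 gave at least the 2 genes that edgeR called, with 2 in the highest other split, so chance cannot be excluded for that count. For the 14 lists past the threshold, 16 of 35 splits gave as many, with up to 22, so chance cannot be excluded for the number of lists either. A list p as small came in 6 splits for fatty acid oxidation (1.35e-05, against 2.44e-09 in the smallest other) and in 3 for adipocyte markers (9.43e-08, against 1.65e-11), so chance cannot be excluded for those lists. As many as the 1676 genes under an unadjusted p of 0.05 in DESeq2's Wald test came in 2 splits, so chance cannot be excluded for that number. For the 161 genes that the Wald test called and the 153 of the likelihood ratio test, 1 of 35 splits gave as many, the real one. That is the smallest share that 35 splits can give, so it does not exclude chance. The margin is narrow, since the next split gave 154 and 133 genes, with 1693 under the unadjusted threshold of the Wald test, and set chow 1 and 3 with HFD+L-NAME 2 and 3, 4 of the 5 libraries with atrial transcripts, against the rest, which points to a structure of the samples of nearly that size.

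Single libraries stood far from the other 3 of their group in 6 of 164 groups of 4, where chance flags about 1 in 20. Cfd was at 1.56 CPM in chow 1 and at most 0.287 in the others. Nr4a3 was at 148.5 CPM in HFD+L-NAME 1 against 21.2 to 33.9, and Pdk4 at 2265 CPM in the same library against 1123 to 1284. Fos was at 120.5 CPM in HFD+L-NAME 3 against 103.7 to 105.7. Mcm6 was at 2.95 CPM in chow 2 against 1.86 to 2.01, and Col1a1 at 66.3 CPM in chow 4 against 119.6 to 124.9.

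Some genes left out of the edgeR test by the low-count filter had most of their counts in 1 or 2 of the treated libraries. The search took only genes with few counts in chow, so genes confined to chow libraries were not looked for. Gbp2b, a guanylate-binding protein gene, had 335 counts in HFD+L-NAME 1 and 191 in HFD+L-NAME 2, against 1 and 8 in HFD+L-NAME 3 and 4 and 0 to 1 in chow. The unnamed gene MGP_C57BL6NJ_G0012552 had 339 and 346 counts in the same libraries and 1 in each of the 6 others. DESeq2's Wald test called both, with log2 fold changes of 9.16 (adjusted p = 0.00470) and 7.76 (0.00432). Its 161 calls thus include genes high in HFD+L-NAME 1 and 2 alone. Ighg2b had 192 counts and Ighv10-1 169 in HFD+L-NAME 3, against at most 2 and 0 in every other library.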

How the results depend on the processing

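Alternatives chosen after seeing the data are the robust fit, the likelihood ratio test, thinning, both marker scores, the fits without several libraries, the lists without some members and the Ighg2c ratio without 1 library. The cause of a change was not tested unless given. Genes changed (all, higher, lower) numbered 161, 88 and 73 with DESeq2's Wald test, 153, 85 and 68 with its likelihood ratio test, and 34, 20 and 14 with no filter on low counts. They numbered 52, 26 and 26 without the 5 libraries with atrial transcripts, a fit whose lone treated library is assumed to vary like chow. They numbered 0, 0 and 0 with limma-voom, either marker score, without HFD+L-NAME 2 and 3 or at an adjusted p under 0.01, and 1, 0 and 1 with the surrogate variable, robust fit or thinning. Leaving out 1 library gave 0 to 3, 0 to 2 and 0 to 1. Other scalings, a mean of 10 counts, a log2 fold change of at least 1, and leaving out named mitochondrial (4 tRNAs, no mRNA) or sex-linked genes gave 2 again. The authors' deposited table held 48 genes at an adjusted p under 0.01 and 1644 at an unadjusted p under 0.05. The count of lists was 0 with an estimated correlation, 0 and 9 with fry directional and mixed, 8 with the atrial score, 6 without HFD+L-NAME 2 and 3, 9 without the 5 libraries, and 7 to 19 without 1 library. Without the matches of F2 and Rps27rt, the ribosomal list had 0.106 without the 5 libraries, and 5 lists instead of 7 passed without HFD+L-NAME 3.

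Adjusted p with an estimated correlation was 0.423 for PPAR targets and adipocytes, 0.782 for oxidative phosphorylation and 0.628 for fatty acid oxidation, matrix, ketone breakdown and glycolysis. Directional fry gave 0.252, 0.258, 0.658, 0.308, 0.620, 0.377 and 0.4003 in that order. Mixed fry gave 0.618, 0.611, 0.0755 and 0.172 for oxidative phosphorylation, matrix, ketone breakdown and glycolysis. With the atrial score these 4 had 0.189, 0.251, 0.0587 and 0.0794. Without HFD+L-NAME 2 and 3, ketone breakdown and glycolysis had 0.514 and 0.514, and oxidative phosphorylation (0.0220) and matrix (0.0504) reversed. Without the 5 libraries, oxidative phosphorylation, ketone breakdown and glycolysis had 0.978, 0.967 and 0.967, and matrix reversed (0.698).

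Other directions reversed too, though the adipocyte score follows the groups, so its reversals cannot be separated from the treatment. With the adipocyte score: oxidative phosphorylation (4.38e-09), matrix (1.69e-08), mesothelial (6.62e-07), fibroblast (5.29e-05), sarcomere (0.00135), macrophage (0.0272), atrial (0.0747), ribosomal (0.0824), tricarboxylic acid and inflammatory (0.0832), and lymphocyte (0.0903). So did the unfolded protein (0.132), adipocyte (0.412, its own genes removed by construction), ketone breakdown (0.450), glycolysis, nitric oxide and erythrocyte (0.502), hypertrophy (0.943) and NADPH (0.986) lists. With the atrial score: unfolded protein (0.250), fibroblast (0.704) and mesothelial (0.198). Without HFD+L-NAME 2 and 3: tricarboxylic acid (0.514), sarcomere (0.179), unfolded protein (0.639), inflammatory (0.403), ribosomal (0.0147), fibroblast (0.0683), lymphocyte (0.721) and mesothelial (0.0778). Without the 5 libraries: tricarboxylic acid (0.606), lipid synthesis and sarcomere (0.967), hypertrophy (0.403), immediate early (0.00185), interferon (0.698), cell cycle (0.969), ribosomal (0.150), fibroblast (0.628) and lymphocyte (0.785). Erythrocyte markers reversed with the surrogate variable (0.953) and RLE factors (0.994), and mesothelial markers on DESeq2 statistics (0.690).

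Leaving out 1 library gave these ranges of adjusted p, beside those of endothelial, immediate early, atrial, hypertrophy, lymphatic and cell cycle genes, which lost a call and whose highest values stand with the results: glycolysis 9.14e-07 to 0.102, oxidative phosphorylation 7.07e-07 to 0.841, matrix 2.12e-11 to 0.140, NRF2 0.338 to 0.998, unfolded protein 0.188 to 0.989, heat shock 0.120 to 0.998, and interferon 0.0412 to 0.980. They were inflammatory 0.00771 to 0.855, ribosomal 0.000719 to 0.299, fibroblast 0.0504 to 0.988, macrophage 0.00544 to 0.899, neutrophil 0.0589 to 0.780, erythrocyte 0.146 to 0.998 and mesothelial 0.183 to 0.988. Other lists gained a call in at least 1 such fit: tricarboxylic acid 0.00387 to 0.679, sarcomere 0.0122 to 0.818, lymphocyte 0.013 to 0.753 and calcium handling 0.0284 to 0.181. So did hypoxia (0.0302 to 0.228), circadian clock (0.033 to 0.827), lipid synthesis (0.0346 to 0.278) and corticoid targets (0.0412 to 0.507). PPAR targets, adipocyte markers, fatty acid oxidation and ketone breakdown passed in all 8 such fits. Log2 fold changes of named genes ranged over these fits from -0.039 to 0.35 for Ucp3, -0.60 to 0.77 for Nppa, -0.14 to 0.27 for Col3a1, -0.078 to 0.059 for Rbm20 and -0.10 to 0.084 for Xbp1. With limma-voom Acta1 was at -0.15 and Xbp1 at 0.0055. At 31522074 to 52053633 counts per library, genes of a few counts limit what can be detected.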

Other observations

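The library HFD+L-NAME 1 had the lowest level of several transcripts, chosen here after their values were seen. Ogdhl, a 2-oxoglutarate dehydrogenase-like gene, was at 4.46 CPM there, at 170 CPM in HFD+L-NAME 2 and at 289 to 369 CPM in the 6 other libraries. Ptprn2, a gene of dense-core vesicles, was at 0.029 CPM there, at 9.61 and 17.2 CPM in HFD+L-NAME 2 and 4 and at 39.8 to 49.997 CPM in the others. Slc6a17 was at 0.029 CPM in the same library and at 2.26 to 7.20 CPM elsewhere. Arhgef19 was at 21.5 to 46.4 CPM in chow and at 1.20 to 9.13 CPM with HFD+L-NAME, so it was lower in every treated library than in any chow library. DESeq2's Wald test called it (log2 fold change -2.60, adjusted p = 0.0122). With edgeR its unadjusted p was under 0.05, but it did not pass.

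Among macrophage markers the members went both ways. The 4 genes named here are outside the rule for naming genes and were chosen after their values were seen. The list's adjusted p missed the threshold, and 4 members rose when adjusted over the list alone. The log2 fold changes of its antigen-presentation genes H2-Ab1 and H2-Eb1 were 0.58 ± 0.12 and 0.54 ± 0.13. That of the monocyte receptor gene Ccr2 was 1.43 ± 0.45, and that of the resident macrophage gene Timd4 was -0.96 ± 0.37. None of these 4 genes passed over all genes with edgeR (6 members of the list had an unadjusted p under 0.05) or limma-voom. With DESeq2, H2-Ab1 (adjusted p = 0.0122) and H2-Eb1 (0.0312) did.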
